A study of Homo sapiens with 69 samples.

How the data were processed

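The libraries profiled human renal proximal tubule epithelial cells, the cells of the first segment of the kidney tubule, by TempO-Seq, a targeted assay in which pairs of detector probes are ligated on their RNA target in a lysate and then sequenced. Primary cells of 2 lots, called lot A and lot B here, were cultured in a microfluidic plate and left untreated or given cisplatin or perfluorooctanoic acid (PFOA). A TERT1-immortalised parent line and its derivatives that over-express the transporter OAT1, OAT3 or OCT2 were cultured in 384-well plates or in the same kind of microfluidic plate, and in the latter were left untreated or given probenecid. The microfluidic plate has units of 3 lanes and is called the chip below. The panel holds probes for 2982 transcripts per the labels, and the deposited table holds 1497 genes in 69 libraries, of which 66 came from cells and 3 were blanks.

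Per the labels, the authors trimmed reads with fastp 0.20.0 and used DESeq2. The aligner, the counting tool and the genome build are not given in the sources used here, and neither are probe positions, so genes are named by the symbols of the deposited table and no coordinates are printed. The authors deposited a signal for each gene and library, which is its read count divided by 1 size factor per library. This was checked on the values: in each library 100% of them were whole multiples of 1 step within a tolerance of 0.01, so whole reads were recovered by dividing by that step. A second deposited file holds only other information, a number per sample for the experiment it came from. The blanks and all primary cells belonged to experiment 1 and all TERT1 cells to experiment 2, so a comparison between these sets cannot be separated from the experiment.

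Cell libraries held 89721 to 2271777 recovered reads. A count of 0 in a library or group was given a floor of 3 reads, divided by the same factors. Each fold against a group without reads was computed from pooled reads against the floor of that group. Since reads of a targeted assay without molecular identifiers are not independent molecules, floors cover counting error only.

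Differences were tested with limma 3.58.1 in R 4.3.3, with a mean-variance trend on log2 of the deposited value plus 1. Genes with a mean under 5 over the libraries of a fit were left out. The 46 TERT1 libraries formed 1 fit with 12 groups, the 20 primary libraries another with 6 groups, and the 11 untreated chip libraries of primary cells and of the parent line a last one. Comparisons over several lines, lots or platforms are means of their differences with equal weights. Interactions asked whether a difference varied between the lines or lots. Benjamini-Hochberg adjustment ran over all genes of a comparison with a threshold of 0.05, and adjusted p-values in the text are limma's. The labels do not say whether replicates were separate cultures, so p-values measure the spread between these libraries. The correlation of replicate-numbered libraries was examined before any fit with a block.

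Gene lists of tubule functions, stress responses, signalling, metabolism and cell types were written before the data were examined, as were the tests, the rule for named genes and all alternatives not described as chosen later. Of the lists, 4 for other cell types (endothelial, distal tubule, podocyte and leukocyte markers) had 0 measured genes, and fibroblast markers, AHR targets and fatty acid synthesis genes had too few to test. Lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. Named genes were, for each comparison, the 6 largest rises and 6 largest falls past the threshold with the same sign in each line, lot or platform, up to 3 of the largest members past it in each list with at least 2 such members, and, whatever their result, the transporters SLC22A6, SLC22A8 and SLC22A2 with the injury and stress genes HAVCR1, LCN2, HMOX1, MDM2 and GDF15. Genes that differ between donors by sex, HLA type or a deleted gene were left out. Levels are normalised read counts as deposited, given as mean ± SD.

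Alternatives were pseudocounts of 0.5 and 5, no filter on low values, a minimum mean of 20, quantile normalisation, rescaling to the same total, array quality weights, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, only the compared groups in the fit, the replicate number as a block, and leaving out each replicate in turn. Chosen after seeing the data were centring each library on its median, leaving out 98 genes whose level switched between replicates, leaving out 6 libraries in doubt, leaving out 1 primary library that did not match its lot, correcting the SD between replicates for group size, and testing that SD between chip and wells. A gene was said to switch when, in at least 5 of the 18 cell groups, its sorted log2 values had a gap of at least 1 and its highest value in that group was above 50. Libraries in doubt had under 200000 reads or a mean correlation with their replicates under 0.9. To match primary libraries with their lot, up to 40 genes that separate the lots were picked for each library from the libraries of other treatments, and the library was placed between the lot means. Its share of the other lot was computed on the scale of the deposited values, over genes at least 5 times higher in that lot. Splits of the same samples into other groups were counted over at most 100 splits. Tests were also run on simulated data, in which 200 genes were changed by known folds and all groups otherwise had the same levels. For the probenecid mean limma recovered 92% of genes changed 2-fold, for the cisplatin mean 68%, and for PFOA 74%. Of genes changed 1.5-fold it recovered 18% for PFOA. With fewer changed genes the adjustment is stricter, and differences between lots were not simulated. These shares therefore do not give the power behind the PFOA counts. Figures and summaries used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.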

Results

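Gene expression was measured in 66 libraries of human proximal tubule cells and in 3 blanks. The series title names the reproducibility and robustness of the chip as its subject. Primary cells on the chip comprised 4 untreated, 3 cisplatin and 3 PFOA libraries of each of 2 lots. The TERT1 lines comprised 5 well libraries each of the parent and OAT1 lines, 6 each of the OAT3 and OCT2 lines, and 3 untreated and 3 probenecid chip libraries of every line. Reads per library ranged from 330783 to 1553168 in primary cells, from 89721 to 1329384 in wells and from 212308 to 2271777 in TERT1 chip libraries. Cell libraries detected 1413 to 1489 of the 1497 genes. The blanks held 613, 280 and 235 reads. Of the 20 primary libraries 1, in the cisplatin group of lot B, did not match its lot, and results are given with it and without it.

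The over-expressing lines each carried reads of their own transporter gene, which untreated parent libraries lacked. SLC22A6, the gene of the organic anion transporter OAT1, stood at 358 ± 163 in OAT1 wells (n = 5) and at 298 ± 45.0 on the OAT1 chip (n = 3). No read of SLC22A6 was found in untreated parent libraries, so it was at least 1097-fold higher in wells and at least 743-fold higher on the chip, against the floor of the pooled parent group. SLC22A8, the gene of OAT3, stood at 18.5 ± 8.13 in OAT3 wells (n = 6) and 32.8 ± 11.8 on the OAT3 chip (n = 3), at least 52.8-fold and 89.7-fold above the parent floor. SLC22A2, the gene of the organic cation transporter OCT2, stood at 13.7 ± 5.40 in OCT2 wells (n = 6) and 18.2 ± 4.38 on the OCT2 chip (n = 3), at least 37.8-fold and 46.9-fold above it. Each of the 8 or 9 libraries of a line carried reads of its gene, while among untreated libraries of other lines 1 OAT3 chip library held 2 reads of SLC22A2 and 1 OCT2 chip library 1 read of SLC22A6. SLC22A2 was below the filter on low values, so its difference was not tested by limma. In untreated primary cells SLC22A6 was low, at 0.660 ± 0.765 in lot A and 7.79 ± 7.20 in lot B (n = 4 each).

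**Figure D1:**
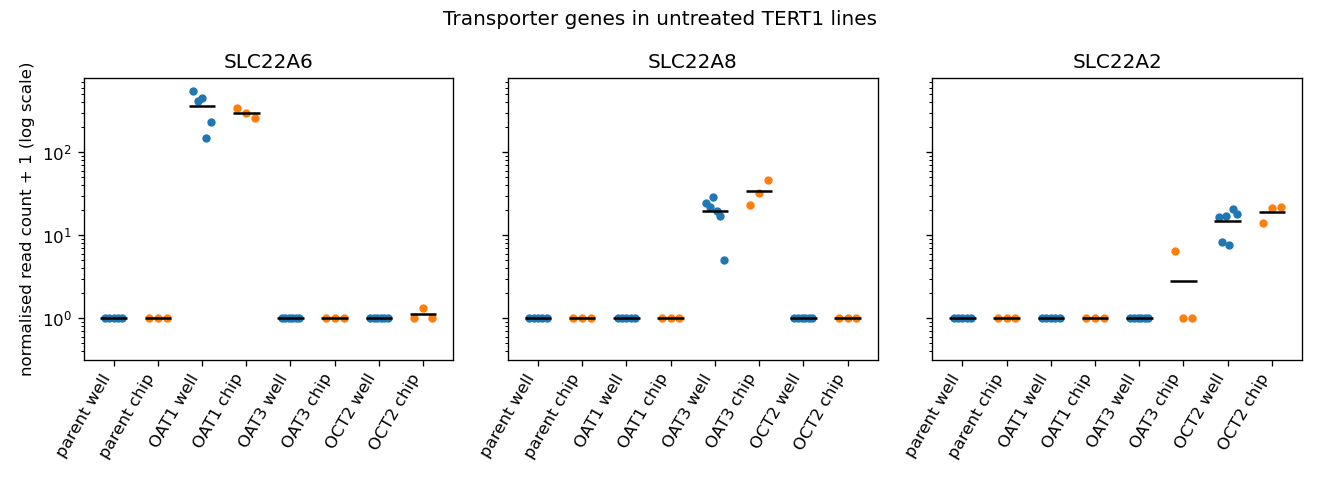
Normalised read count plus 1 (log axis) of SLC22A6, SLC22A8 and SLC22A2 in each untreated library of the 4 TERT1 lines, in wells (blue) and on the chip (orange), with bars at the group means. Reads of SLC22A6 lie near 300 in the OAT1 line, while parent libraries lie at 1, the position of a count of 0.

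The OAT1 line was compared with the parent line to see what else differs between these cells besides the transporter. SLCO2B1, another organic anion transporter gene, was at 193 ± 34.4 in OAT1 wells against 0.0993 ± 0.222 in parent wells (n = 5 each), and was higher in 8 of 8 OAT1 libraries (adjusted p = 8.16e-26). The matrix collagenase gene MMP1 was 66.2-fold higher, the complement gene C3 24.3-fold and the growth factor gene AREG 8.41-fold. LCN2, the gene of the injury marker NGAL, was at 476 ± 227 on the OAT1 chip against 2.23 ± 1.04 on the parent chip (n = 3 each). HAVCR1, the gene of the injury marker KIM-1 and 1 of the genes whose level switched between replicates, was 4.81-fold lower, in 8 of 8 libraries (adjusted p = 1.59e-07). ESRP1, an epithelial splicing regulator, was at 214 ± 32.1 in parent wells and had no reads in OAT1 libraries, at least 373-fold lower in wells and at least 258-fold lower on the chip. MAOA, which encodes the mitochondrial enzyme monoamine oxidase A, was lower, at 0.110 ± 0.247 in OAT1 wells against 58.5 ± 17.7 in parent wells, and the metabolic coactivator gene PPARGC1A 5.35-fold lower. The stress cytokine gene GDF15 was 5.50-fold lower. The heme oxygenase gene HMOX1 gave a log2 difference of 0.62 (SE 0.22, adjusted p = 0.0291), which did not pass without parent well replicate 1, parent chip replicate 2, OAT1 well replicate 5 or OAT1 chip replicate 1 or 2 (adjusted p = 0.0532 to 0.116), nor after quantile normalisation (0.102), after median centring (0.0693), without libraries in doubt (0.0592) or with only the compared groups in the fit (0.0876). MDM2, a switching gene that encodes a ligase restraining p53, did not pass (adjusted p = 0.124, or 0.0293 with only the compared groups in the fit). Of 3 tested fibroblast markers, S100A4 was higher by a log2 difference of 0.55 (adjusted p = 0.0291), and ACTA2 and DCN, both switching genes, did not pass.

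Interferon response genes were higher in the OAT1 line: 6 of 9 measured members rose and 0 fell, 9 and 0 adjusted over the list alone (camera adjusted p = 0.00043; adjusted p = 0.067 with an estimated correlation). Among them IFI27 rose 26.1-fold and the exonuclease gene ISG20 6.45-fold. Of 12 NF-kB and inflammation genes 7 rose and 2 fell, 8 and 2 adjusted over the list alone (camera adjusted p = 0.011; adjusted p = 0.22 with an estimated correlation), with the inhibitor gene TNFAIP3 and the chemokine gene CXCL8 (3.19-fold) among the risers. Metallothioneins, which bind metals, were lower, with 0 risen and 5 fallen of 7 in both counts (camera adjusted p = 0.00085; adjusted p = 0.067 with an estimated correlation), such as MT2A at 2.99-fold and MT1G at 2.46-fold lower. Of 6 CAR and PXR targets, genes of drug metabolism, 3 rose and 0 fell in both counts (camera adjusted p = 0.033; adjusted p = 0.067 with an estimated correlation). Members of that list in the UGT1A family share exons, so their assignment is uncertain. The adhesion gene CDH1, which encodes E-cadherin, rose 4.07-fold. In all, 254 of 1456 genes rose and 217 fell, and the split was 224 and 322 after quantile normalisation and 205 and 340 after median centring, a setting chosen later.

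In the OAT3 line, genes of cell cycle and proliferation were higher than in the parent. Of 34 measured, 22 rose and 0 fell, 28 and 0 adjusted over the list alone (camera adjusted p = 7.2e-09; adjusted p = 0.28 with an estimated correlation). The replication factor genes CDC45 and CDC6 rose 2.73-fold and 2.17-fold. Hypoxia and glycolysis genes were lower, with 0 risen and 10 fallen of 17, 0 and 12 adjusted over the list alone (camera adjusted p = 8.7e-07; adjusted p = 0.13 with an estimated correlation). NDRG1, a gene induced by low oxygen, fell 3.33-fold and the glycolytic enzyme gene ENO2 2.13-fold. Immediate early genes, which respond fast to growth signals, were lower as well, with 1 risen and 8 fallen of 11, 1 and 9 adjusted over the list alone (camera adjusted p = 0.00027; adjusted p = 0.096 with an estimated correlation).

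Of 18 mesenchymal and matrix genes 9 rose and 2 fell in the OAT3 line, 10 and 2 adjusted over the list alone (camera adjusted p = 0.010, or 0.16 with an estimated correlation). CDH2, the gene of N-cadherin, was at 264 ± 106 in OAT3 wells (n = 6) against 0.239 ± 0.336 in parent wells (n = 5), and was higher in 9 of 9 libraries (adjusted p = 2.03e-20). It was also higher than in the parent in 8 of 8 untreated primary tubule libraries, so CDH2 alone does not mark a mesenchymal change. SNAI2, a transcription factor of epithelial to mesenchymal change, rose 40.5-fold. DCN, a fibroblast marker and a switching gene, rose by a log2 difference of 3.51, while the markers S100A4 and ACTA2 did not pass. MYL9, a myosin light chain gene on that list, had no reads in OAT3 libraries and was at least 42.7-fold lower in wells and at least 19.8-fold lower on the chip. Of 10 sterol synthesis genes 0 rose and 2 fell in both counts (camera adjusted p = 0.029; adjusted p = 0.59 with an estimated correlation). The heparan sulfate enzyme gene HS6ST2 fell 36.4-fold and the bile acid receptor gene NR1H4 7.39-fold. The serine protease gene PRSS8 had no reads in OAT3 wells, at least 74.3-fold lower than in parent wells. LCN2 was higher, at 31.8 ± 13.3 on the OAT3 chip against 2.23 ± 1.04 on the parent chip (n = 3 each), while GDF15 was 1.89-fold lower. HMOX1 gave a log2 difference of -0.61 (SE 0.22, adjusted p = 0.0377), which did not pass without parent well replicate 5, parent chip replicate 1 or 3, OAT3 well replicate 3, 4 or 6 or OAT3 chip replicate 2 or 3 (adjusted p = 0.0501 to 0.201), nor with only the compared groups in the fit (0.123). The switching genes HAVCR1 and MDM2 gave log2 differences of -0.26 (SE 0.31, adjusted p = 0.597) and 0.22 (SE 0.98, adjusted p = 0.911). In all, 203 of 1456 genes rose and 135 fell, against 187 and 220 after quantile normalisation and 160 and 229 after median centring. Of the well libraries of this line, 2 are among the 6 in doubt.

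The comparisons of the OAT1, OAT3 and OCT2 lines share the same parent libraries, so a difference that recurs between them is not an independent repeat. The OCT2 line differed from the parent in fewer genes, 59 up and 60 down, and again in mesenchymal genes. Of 18 measured, 6 rose and 1 fell, 7 and 2 adjusted over the list alone (camera adjusted p = 2.2e-06; adjusted p = 0.0053 with an estimated correlation). CDH2, which was also higher in primary tubule cells than in the parent, was at 553 ± 54.6 in OCT2 wells (n = 6) and 480.1 ± 19.0 on the chip (n = 3). It was higher than in the parent in 9 of 9 OCT2 libraries (adjusted p = 8.84e-22). SNAI2 rose 18.7-fold and MMP1 22.0-fold, and SLCO2B1 rose to 23.8 ± 10.1 in OCT2 wells. Of the fibroblast markers DCN, a switching gene, rose by a log2 difference of 2.86, and S100A4 and ACTA2 did not pass. Of 12 NF-kB and inflammation genes 3 rose and 0 fell in both counts (camera adjusted p = 0.0031; adjusted p = 0.18 with an estimated correlation), among them C3 at 6.31-fold. Immediate early genes had 0 risen and 4 fallen of 11, 0 and 5 adjusted over the list alone (camera adjusted p = 0.016; adjusted p = 0.18 with an estimated correlation), and EGR1, a transcription factor of this class, fell 2.93-fold. Of 7 metallothioneins 1 rose and 0 fell in both counts (camera adjusted p = 0.038; adjusted p = 0.25 with an estimated correlation). ESRP1 fell 7.12-fold and PRSS8 8.33-fold, while the glutathione transferase gene GSTM3 had no reads in OCT2 wells, at least 80.4-fold below the parent. GDF15 was 1.57-fold and HMOX1 1.73-fold lower, and the switching gene HAVCR1 2.11-fold higher. Without parent chip replicate 3 neither HMOX1 (adjusted p = 0.0557) nor HAVCR1 (adjusted p = 0.0635) passed, and HMOX1 did not without OCT2 chip replicate 1 (adjusted p = 0.0667). LCN2 gave a log2 difference of 0.40 (SE 0.29, adjusted p = 0.529) and MDM2, also switching, one of -0.20 (SE 0.98, adjusted p = 0.968). With DESeq2 200 genes passed the threshold, without the libraries in doubt 179, and rescaled to the same total 72 rose and 46 fell.

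The chip was compared with wells within each untreated line to ask how the culture platform alters the profile. Immediate early genes were lower on the chip. Of 11 measured, 1 rose and 9 fell, the same counts adjusted over the list alone (camera adjusted p = 0.0025; adjusted p = 0.16 with an estimated correlation). EGR1 stood at 293 ± 102 in parent wells (n = 5) and 46.8 ± 20.2 on the parent chip (n = 3), was 6.39-fold lower over the 4 lines, and was lower in 12 of 12 chip libraries (adjusted p = 4.91e-15). DUSP6, a phosphatase gene that restrains ERK signalling, was 4.10-fold lower, and CSRNP1, a nuclear protein gene, went from 199 ± 17.8 to 53.0 ± 8.95 in the parent. FKBP5, a chaperone gene induced by glucocorticoids, was 4.45-fold higher in 12 of 12 chip libraries (adjusted p = 1.69e-15), with 72.5 ± 14.7 in OCT2 wells (n = 6) and 350.0 ± 86.5 on the OCT2 chip (n = 3).

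Among other genes higher on the chip, ABCB1, the gene of the efflux pump P-glycoprotein, was 3.41-fold higher, the complement protease gene C1S 4.54-fold, and SPP1, the gene of osteopontin, 2.26-fold. MAOA was higher, at 58.5 ± 17.7 in parent wells (n = 5) and 194 ± 13.9 on the parent chip (n = 3). LCN2 was higher in 12 of 12 chip libraries, by a mean log2 difference of 2.57 over the lines, though parent wells had no reads of it. In the OAT1 line it stood at 27.7 ± 5.60 in wells (n = 5) and 476 ± 227 on the chip (n = 3). GDF15 was 1.48-fold and HMOX1 1.83-fold lower. The switching genes HAVCR1 and MDM2 gave log2 differences of 0.40 (SE 0.22, adjusted p = 0.111) and -0.32 (SE 0.69, adjusted p = 0.708), and HAVCR1 passed without OAT1 well replicate 1 (adjusted p = 0.0356), after quantile normalisation (0.0232), at the same total (0.0485) and after median centring (0.0285). In sterol synthesis 6 of 10 genes rose and 3 fell in both counts, with IDI1 3.41-fold higher and the lanosterol synthase gene LSS 4.32-fold lower, and the list as a whole did not pass (camera adjusted p = 0.22). The autophagy receptor gene SQSTM1 was 4.86-fold lower, the glycolytic gene PGAM1 2.60-fold and the fibroblast marker S100A4 4.81-fold. Of the other fibroblast markers, both switching genes, ACTA2 was 1.97-fold lower and DCN 2.91-fold higher. In all, 350 of 1456 genes were higher and 510 lower on the chip, against 467 and 448 after quantile normalisation and 456 and 439 after median centring.

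By line, 135 genes were higher and 309 lower on the chip in the parent, 198 and 330 in OAT1, 185 and 356 in OAT3, and 235 and 308 in OCT2. The platform difference varied between lines for 114 genes, such as SPP1, whose wells stood at 863 ± 74.1 in OAT1 (n = 5) and 2914 ± 258 in the parent (n = 5) and whose chips stood at 3556 ± 118 and 5220.0 ± 931 (n = 3 each). SPP1 was picked from the interaction after its values were seen. In the parent line all genes together shifted by a median log2 of -0.20, and the parent count fell to 258 without parent chip replicate 3. The interaction count rose to 182 without OAT3 well replicate 1 and to 193 without the libraries in doubt. Titles of TERT1 chip libraries differ from those of well libraries in 3 codes whose meaning is not given in the sources used here, so whatever these stand for goes with the platform. The last of them, a letter, is the same in all wells and differs between the lines on the chip, so on the chip it goes with the line as well.

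Probenecid, a drug that blocks organic anion transporters, was compared with no treatment on the chip in each TERT1 line. Cell cycle and proliferation genes fell: 26 of 34 were lower and 0 higher, 30 and 0 adjusted over the list alone (camera adjusted p = 1.1e-35; adjusted p = 0.0047 with an estimated correlation). MKI67, the gene of the proliferation marker Ki-67, went from 121 ± 36.6 to 23.7 ± 4.03 in the parent line (n = 3 each), was 3.57-fold lower over the 4 lines and lower in 12 of 12 treated libraries (adjusted p = 1.49e-07). The mitotic kinesin genes KIF2C and KIF20A both fell, by 3.17-fold and 3.17-fold, and BIRC5, the gene of survivin, fell 3.10-fold. NRF2 and oxidative stress genes rose, with 11 up and 0 down of 17, 13 and 0 adjusted over the list alone (camera adjusted p = 0.00014; adjusted p = 0.046 with an estimated correlation). EPHX1, an epoxide hydrolase gene, rose 2.14-fold and GCLC, the limiting enzyme of glutathione synthesis, 2.06-fold. Of that list's 17 genes 4 are among those whose level switched between replicates.

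Mesenchymal and matrix genes fell under probenecid, with 8 down and 0 up of 18 in both counts (camera adjusted p = 6.5e-05; adjusted p = 0.015 with an estimated correlation). The matrix-associated growth factor gene CTGF fell 2.53-fold and the matrix glycoprotein gene THBS1 2.05-fold. Of 12 NF-kB and inflammation genes 4 fell and 0 rose in both counts (camera adjusted p = 0.00014; adjusted p = 0.046 with an estimated correlation), with CXCL8 3.11-fold lower. Of 17 hypoxia and glycolysis genes 5 fell and 0 rose in both counts (camera adjusted p = 0.029; adjusted p = 0.79 with an estimated correlation). Outside these lists the homeobox gene HOXD8 rose 2.12-fold, in 12 of 12 libraries (adjusted p = 1.25e-11), the serine synthesis gene PSAT1 2.29-fold and the stress transcription factor gene ATF5 1.97-fold. SLC22A6 was at 298 ± 45.0 on the untreated OAT1 chip and 179.8 ± 27.2 with probenecid (n = 3 each), a log2 difference of -0.73 (SE 0.28) that did not pass in that line (adjusted p = 0.0881). HMOX1 rose 1.46-fold, but did not pass without untreated replicate 3 of OAT1 (adjusted p = 0.0507) or OAT3 (adjusted p = 0.0571). The switching gene HAVCR1 gave a log2 difference of -0.68 (SE 0.25, adjusted p = 0.0406). It did not pass without parent untreated replicate 1 or 2 or probenecid replicate 1, OAT1 untreated replicate 1 or probenecid replicate 1 or 2, or untreated or probenecid replicate 1 or 3 of OCT2 or OAT3 (adjusted p = 0.0520 to 0.0827). Log2 differences were 0.07 for GDF15 (adjusted p = 0.687), -0.22 for LCN2 (adjusted p = 0.524) and 1.31 for the switching gene MDM2 (adjusted p = 0.234).

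**Figure D2:**
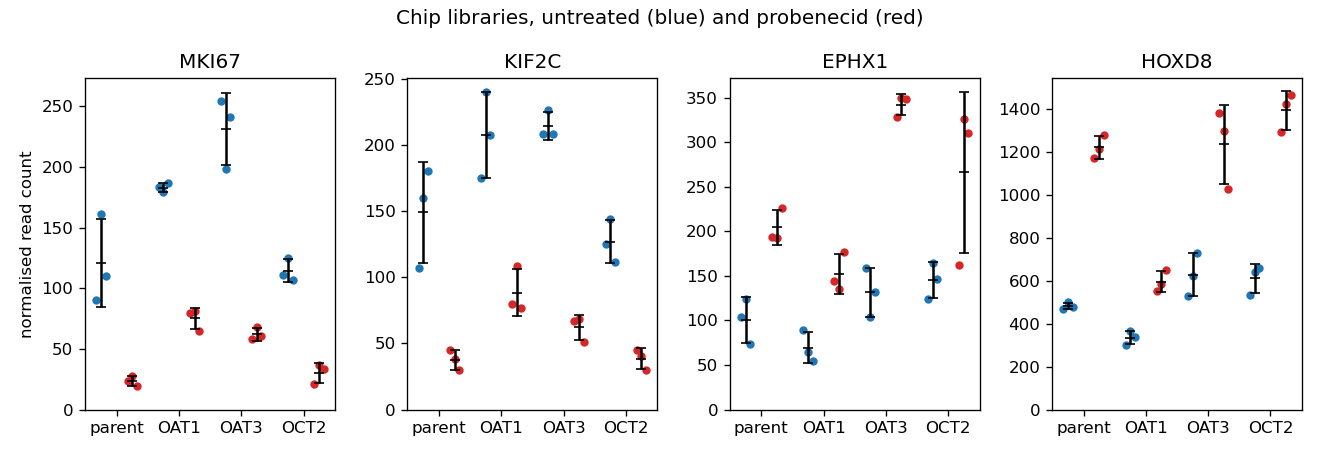
Normalised read counts of MKI67, KIF2C, EPHX1 and HOXD8 in untreated (blue) and probenecid (red) chip libraries of the 4 TERT1 lines, as points with mean and SD (n = 3 per group). MKI67 falls from 121 ± 36.6 to 23.7 ± 4.03 in the parent line, and HOXD8 rises from 482 ± 15.4 to 1221 ± 54.5.

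In all, probenecid raised 235 of 1456 genes and lowered 124, with a median log2 shift of all genes of 0.14 (0.13 in the parent, 0.26 in OAT1, 0.14 in OAT3 and 0.03 in OCT2). This split was 184 and 155 after quantile normalisation, 163 and 144 rescaled to the same total, 138 and 203 with edgeR, 169 and 211 with DESeq2 and 159 and 147 after median centring. By line, 8 genes rose and 43 fell in the parent (25 and 97 with edgeR, 29 and 122 with DESeq2), 100 and 48 in OAT1 (25 and 82 with edgeR, 31 and 92 with DESeq2), 38 and 63 in OAT3, and 13 and 50 in OCT2. The difference between lines passed for 6 genes, all named here after their values were seen: SNAI2, MMP1, ENO2, CXCL8, CXCL1 and ANXA2. CXCL1, a chemokine gene, went from 5312 ± 918 to 1746 ± 413 in the parent and from 26818 ± 4151 to 29585 ± 8738 in OAT1 (n = 3 each). This count fell to 0 without parent probenecid replicate 3, OAT1 untreated replicate 1 or 3, OAT1 probenecid replicate 1 or 2, OCT2 untreated replicate 1 or OCT2 probenecid replicate 2. It was 2 without OAT1 untreated replicate 2 or OCT2 untreated replicate 3, and 3 without parent untreated replicate 3, parent probenecid replicate 1 or OAT3 untreated replicate 2. Within lines, the parent count was 26 without probenecid replicate 3, the OAT1 count 70, 75, 80 and 70 without untreated replicate 1 and probenecid replicates 1, 2 and 3, and the OCT2 count 34, 35 and 33 without untreated replicates 1 and 3 and probenecid replicate 2.

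Cisplatin, a platinum drug that damages DNA and is toxic to the proximal tubule, was compared with no treatment in both primary lots. Targets of p53 and DNA damage rose: 13 of 18 were higher and 0 lower, 15 and 0 adjusted over the list alone (camera adjusted p = 1.5e-06; adjusted p = 0.13 with an estimated correlation). FAS, a death receptor gene, went from 93.5 ± 12.2 to 363 ± 43.2 in lot A and from 26.6 ± 10.0 to 134 ± 95.2 in lot B (n = 4 untreated and 3 treated per lot), and was higher in 6 of 6 treated libraries (adjusted p = 2.51e-05). The cell death gene BBC3, which encodes PUMA, rose 2.60-fold and GDF15 1.65-fold. MDM2 rose 20.5-fold, but it is 1 of 5 members of this list whose level switched between replicates. Of 16 apoptosis genes 6 rose and 0 fell, 7 and 0 adjusted over the list alone (camera adjusted p = 0.0085; adjusted p = 0.33 with an estimated correlation).

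Genes of proximal tubule differentiation fell with cisplatin. Of 7 measured, 0 rose and 5 fell, 0 and 6 adjusted over the list alone (camera adjusted p = 0.00012; adjusted p = 0.11 with an estimated correlation). AQP1, the water channel gene of this segment, fell 5.89-fold and the fatty acid transport gene SLC27A2 3.91-fold. FABP1, the fatty acid binding protein gene, went from 168 ± 26.3 to 0.908 ± 0.915 in lot A and from 216 ± 47.6 to 15.5 ± 11.3 in lot B, lower in 6 of 6 libraries (adjusted p = 6.13e-09). Of 18 kidney injury genes 2 rose and 7 fell in both counts (camera adjusted p = 0.031; adjusted p = 0.54 with an estimated correlation), and the fallen included the adhesion gene VCAM1 at 3.92-fold and FABP1. HAVCR1, which switched between replicates, gave a log2 difference of 0.73 (SE 0.65, adjusted p = 0.434) and LCN2 one of 0.57 (SE 0.36, adjusted p = 0.263, or 0.0437 without lot B cisplatin replicate 2 and 0.0137 with array weights). HMOX1 fell 2.60-fold.

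Hypoxia and glycolysis genes also fell with cisplatin, with 15 down and 0 up of 20, 16 and 0 adjusted over the list alone (camera adjusted p = 2.4e-12; adjusted p = 0.12 with an estimated correlation). NDRG1 fell 16.8-fold, the carbonic anhydrase gene CA9 17.9-fold and the vasodilator peptide gene ADM 15.1-fold. In cell cycle and proliferation 14 of 31 genes fell and 3 rose, 15 and 3 adjusted over the list alone (camera adjusted p = 1.5e-05; adjusted p = 0.16 with an estimated correlation), with the mitotic gene HMMR 9.33-fold lower. Of 8 metallothioneins 5 fell and 0 rose in both counts (camera adjusted p = 0.00073; adjusted p = 0.16 with an estimated correlation), among them MT1H, which went from 103 ± 22.9 to 6.32 ± 1.46 in lot B. Of 10 sterol synthesis genes 4 fell and 0 rose in both counts (camera adjusted p = 0.0022; adjusted p = 0.33 with an estimated correlation), INSIG1, which restrains this pathway, by 7.50-fold. Of 19 mesenchymal genes 8 fell and 2 rose in both counts (camera adjusted p = 0.0031; adjusted p = 0.33 with an estimated correlation). The fibroblast marker ACTA2, a switching gene, gave a log2 difference of -1.15 (adjusted p = 0.000118), while LUM and DCN did not pass. Of 18 ER stress and ATF4 genes 5 fell and 1 rose in both counts (camera adjusted p = 0.0089; adjusted p = 0.47 with an estimated correlation), and the riser was PSAT1 at 3.17-fold. The chemokine gene CCL2 rose 3.89-fold and AREG 3.65-fold.

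**Figure D3:**
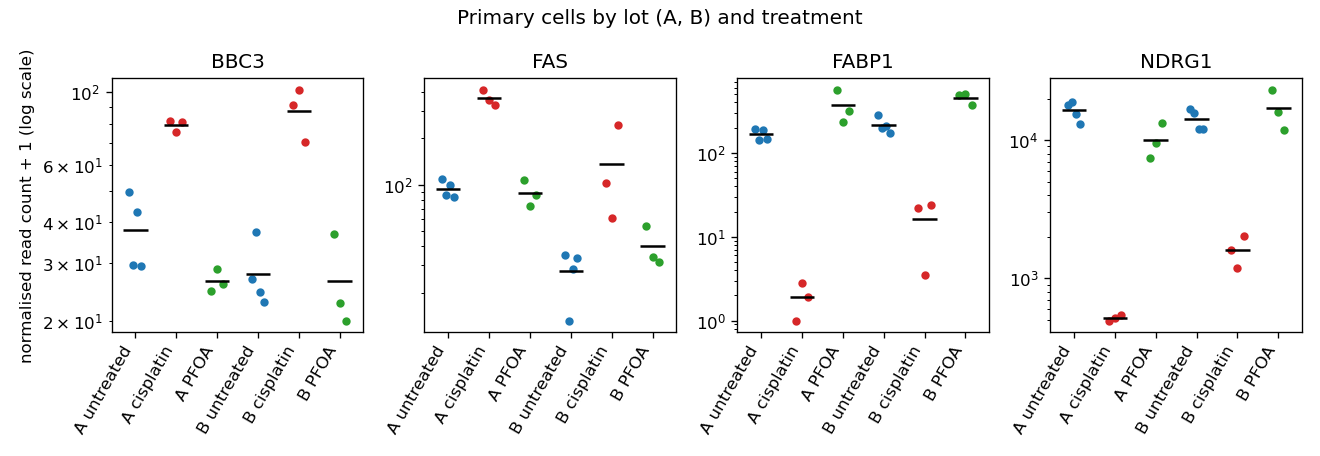
Normalised read count plus 1 (log axis) of BBC3, FAS, FABP1 and NDRG1 in each primary library, by lot and treatment (blue untreated, red cisplatin, green PFOA), with bars at the group means (n = 4 untreated, 3 cisplatin and 3 PFOA per lot). Cisplatin libraries of lot A have a mean of 0.908 reads of FABP1 against 168 untreated.

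In all, cisplatin raised 249 of 1460 genes and lowered 184, with a median log2 shift of all genes of 0.13. The split was 425 and 191 rescaled to the same total and 258 and 306 after median centring. Lot A gave 105 up and 184 down and lot B 102 and 67, with a median shift of 0.26 in lot B. The difference between lots passed for 35 genes, among them CA9, which went from 529 ± 46.3 to 9.83 ± 5.11 in lot A and from 517 ± 156 to 81.8 ± 14.8 in lot B (n = 4 and 3). Lot B's count was 391 without its cisplatin replicate 2 (339 up and 52 down), and lot A's was 184 without cisplatin replicate 1 and 181 without replicate 3. The count of 35 was 17, 14 and 13 without lot A cisplatin replicates 1, 2 and 3, it was 21, 16, 19 and 21 without lot A untreated replicates 1 to 4, and it was 17, 93 and 20 without lot B cisplatin replicates 1 and 2 and untreated replicate 3.

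The cisplatin library that did not match its lot changes some of these results. On genes that separate the lots it lay at 0.145 of the way from lot A to lot B, while each of the other 19 primary libraries lay at 0.741 or more of the way to its own lot. With switching genes left out, its correlation was 0.932 to 0.940 with cisplatin libraries of lot A and 0.897 to 0.911 with its replicates. Over 18 genes higher in lot A its share of the lot A level had a median of 0.531 (quartiles 0.439 and 0.576). Without it cisplatin raised 179 genes and lowered 242 over the mean of the lots, and the median shift was -0.01. The 351 genes past the threshold both with and without it had the same sign, and the 10 lists called with it were also called without it, with 12 of 18 targets of p53 higher and 15 of 20 hypoxia genes lower. Lot B then gave 58 up and 124 down and lot A 150 and 222. Across genes the differences of the lots had r = 0.636 with it and 0.4929 without, where genes are not independent replicates. All 116 genes past in both lots had the same sign with it, and 119 of 122 without. Levels of lot B cisplatin cells in the text and the figure include it.

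PFOA, a perfluorinated surfactant that activates the fatty acid sensor PPAR alpha in liver cells, was compared with no treatment in the same lots. Genes of PPAR alpha and fatty acid oxidation leaned upward as a list, with a median log2 difference of 0.28 over 14 genes (camera adjusted p = 0.0023; adjusted p = 0.72 with an estimated correlation), and 0 of them passed the test, also adjusted over the list alone. FABP1, a member of that list picked after its values were seen, was at 370.0 ± 172 against 168 ± 26.3 in lot A and 455 ± 70.2 against 216 ± 47.6 in lot B (n = 3 and 4), a log2 difference of 1.06 (SE 0.37) that did not pass (adjusted p = 0.990). The switching gene MDM2 differed by 1.69 (SE 0.75), HAVCR1, also switching, by -0.10 (SE 0.65), LCN2 by -0.89 (SE 0.36), HMOX1 by 0.06 (SE 0.14) and GDF15 by -0.33 (SE 0.17) on the log2 scale, each with an adjusted p of 0.997. Over the mean of the lots limma called 0 of 1460 genes at the threshold and 60 at an unadjusted p under 0.05. Lot A gave 0 and 80, and lot B 0 and 87. The tool edgeR called 0 in each, while DESeq2 called 14 for the mean, 7 in lot A and 8 in lot B. The difference between lots passed for 0 genes by limma (91 unadjusted), and the lots' differences had r = -0.085 across genes. All genes shifted by a median log2 of -0.14 in lot A and 0.25 in lot B. The count of 0 became 1 in lot A without PFOA replicate 3, 1 in lot B without PFOA replicate 2 or untreated replicate 1, and 1 for the difference between lots without lot B PFOA replicate 1.

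Cisplatin and PFOA were also compared directly. Cisplatin libraries were higher in 178 and lower in 170 of 1460 genes, or 327 and 190 rescaled to the same total. Targets of p53 and DNA damage were higher with cisplatin, 13 of 18 with 0 lower, 15 and 0 adjusted over the list alone (camera adjusted p = 1.2e-07; adjusted p = 0.087 with an estimated correlation). Hypoxia and glycolysis genes were lower in 15 of 20 with 0 higher, 17 and 0 adjusted over the list alone (camera adjusted p = 6.3e-12; adjusted p = 0.087 with an estimated correlation). Proximal tubule differentiation genes were lower in 5 of 7 with 0 higher in both counts (camera adjusted p = 0.00023; adjusted p = 0.087 with an estimated correlation). The other 7 lists called, of which the apoptosis genes were higher and the rest lower, had adjusted p-values of 0.25 to 0.50 with an estimated correlation. With DESeq2 558 genes passed, and without the libraries in doubt 525. Without the library that did not match its lot the split was 151 and 265, and 9 of the 10 lists were called, with mesenchymal genes no longer among them.

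Untreated primary cells were set against the untreated parent line on the chip to show how this 1 line differs from cells taken from kidney. The lines derived from it were not compared with primary cells, so these differences need not hold for TERT1 cells in general. Genes of proximal tubule differentiation were higher in primary cells, 5 of 7 with 0 lower in both counts (camera adjusted p = 0.0099; adjusted p = 0.24 with an estimated correlation). AQP1 was at 171 ± 21.4 in lot A and 362 ± 122 in lot B (n = 4 each) against 0.732 ± 0.771 in the parent line (n = 3). PLIN2, a lipid droplet protein gene, had no reads in the parent chip and was at least 4153-fold higher in lot A and at least 3534-fold higher in lot B. VCAM1 stood at 9566 ± 329 in lot A and 5136 ± 630.4 in lot B against 0.647 ± 0.442, higher in 8 of 8 libraries (adjusted p = 3.44e-13). TERT, the telomerase gene used to immortalise the line, was at 134 ± 43.2 in the parent and had no reads in either lot, at least 226-fold and 333-fold lower. Fibroblast markers differed as well. LUM had no reads in the parent chip and was at least 217-fold higher in lot A and at least 119.5-fold higher in lot B. ACTA2, a switching gene, was 7.75-fold higher. S100A4 was lower, at 0.477 ± 0.953 in lot A and 1.29 ± 1.35 in lot B against 35.9 ± 8.93, and DCN, a switching gene, did not pass.

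Cell cycle genes were lower in primary cells, with 26 of 34 down and 1 up, 27 and 1 adjusted over the list alone (camera adjusted p = 0.00077; adjusted p = 0.32 with an estimated correlation), and the mitotic kinase gene PBK was 13.2-fold lower. Hypoxia and glycolysis genes had 11 up and 3 down of 20, 12 and 3 adjusted over the list alone (camera adjusted p = 0.0099; adjusted p = 0.32 with an estimated correlation), with NDRG1 28.7-fold higher and CA9 at 529 ± 46.3 in lot A and 517 ± 156 in lot B against 0.384 ± 0.665. Of 14 genes of PPAR alpha and fatty acid oxidation 8 were higher and 3 lower (camera adjusted p = 0.027; adjusted p = 0.32 with an estimated correlation), of 6 CAR and PXR targets 5 and 0 (camera adjusted p = 0.027; adjusted p = 0.24 with an estimated correlation), and of 18 ER stress genes 10 and 2 (camera adjusted p = 0.043; adjusted p = 0.32 with an estimated correlation), with the same counts adjusted over each list alone. Of 9 proximal tubule transporters 6 were higher and 1 lower in both counts, and of 15 genes of oxidative phosphorylation 10 and 3 (camera adjusted p = 0.0499 for each; adjusted p = 0.32 for each with an estimated correlation). CDH2 was 339-fold higher, while CDH1 was 10.2-fold lower and the sterol gene IDI1 9.45-fold lower. CDH2 was also higher than in the parent in every untreated OAT3 and OCT2 library, so its low level is not shared by all TERT1 lines. HMOX1 was 22.6-fold higher, the switching gene HAVCR1 9.13-fold and LCN2 2.73-fold, though LCN2 did not pass after quantile normalisation (adjusted p = 0.0575). GDF15 gave a log2 difference of 0.37 (SE 0.22, adjusted p = 0.159), or an adjusted p of 0.0453 without lot B replicate 4 and 0.0271 after quantile normalisation. The switching gene MDM2 gave one of 2.39 (SE 0.95, adjusted p = 0.0452), which did not pass without lot A replicate 2, 3 or 4, lot B replicate 1, 2 or 3 or parent replicate 1 or 3 (adjusted p = 0.0543 to 0.233), nor after quantile normalisation (0.0658) or with array weights (0.120). In all, 433 of 1486 genes were higher and 520 lower, with a median log2 shift of -0.19. The cell types were cultured in different experiments, so cell type and experiment cannot be told apart here.

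Reproducibility was described as the spread of log2 values between replicates over 1487 genes. The median SD of a group ranged from 0.155 in untreated OCT2 chips to 0.645 in cisplatin chips of lot B. The widest group includes the library that did not match its lot. Over untreated groups the mean was 0.370 in wells, 0.267 on TERT1 chips and 0.353 in primary chips. Corrected for group size, which was chosen after seeing the data as was the next test, these became 0.400, 0.321 and 0.398. Untreated chips had a lower corrected value than wells in 4 of 4 lines, by a mean difference of -0.0798. An exact two-sided permutation test could not call this at this number of lines (p = 0.125, the smallest it allows). In the parent and OCT2 lines every untreated chip library had more reads than every well library, so depth went with the platform there. In the OAT1 and OAT3 lines depths overlapped. With probenecid, OCT2 chips had a corrected value of 0.354 against 0.257 in OCT2 wells, while probenecid chips of the other lines stayed below their wells. In the parent line the values rest on single libraries. The uncorrected mean was 0.332 in wells without parent well replicate 5, and 0.220 on TERT1 chips without parent chip replicate 3. Without that well library alone, parent wells spread less than parent chips. The median correlation between replicates with switching genes kept ranged from 0.878 in lot B cisplatin to 0.969 in OAT1 probenecid chips. Without the libraries in doubt the uncorrected mean was 0.315 in wells and 0.279 in untreated primary cells. Within this spread, 98 genes had levels that switched between replicates of a group, among them HAVCR1, MDM2, NQO1 and VEGFA, so single values of these genes carry little weight.

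**Figure D4:**
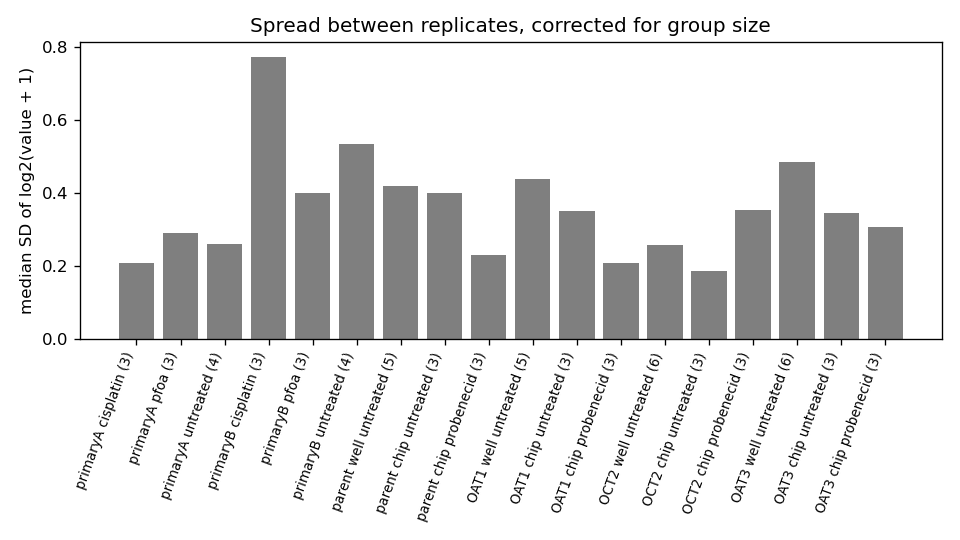
Median over 1487 genes of the SD of log2(value + 1) between replicates of each group, corrected for group size (chosen after seeing the data), with the number of libraries in brackets. Lot B cisplatin has the tallest bar at 0.775 and untreated OCT2 chips the lowest at 0.186.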

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

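The test of a lot B library holding RNA of lot A, the match of libraries with their lots and the rule that picks genes switching between replicates were chosen only after results were seen, and the other tests before theirs. After values were seen, the lot B spread was changed from the median SD to the mean SD that its prediction names, and the test of a single lot B library, whose bar was met since 391 reached lot A's 289, was read as open once a library that did not match its lot was found. The first pattern is a set of 98 genes, MDM2 and HAVCR1 among them, whose level jumped between high and low from replicate to replicate. Poisson noise at the recovered depths is argued against, since 20 simulated sets gave at most 0 such genes. All replicate pairs spread wider than Poisson noise, with a chi-square per degree of freedom of at least 8.54. Noise of that width was not simulated and stays open. Whole libraries in another state stay open: the number of genes at their low level varied between libraries 1.47 times as much as after shuffling within groups (permutation p = 0.001, the smallest that 1000 shuffles can give), which lies between the bounds set for and against this. A property of the gene on the panel, such as probes that sometimes fail, is a candidate explanation, since 75.6% of the 90 genes picked in TERT1 groups alone showed the gaps in at least 2 of 6 primary groups, against 10.0% of 1407 other genes. A biological source in the cells was not tested and stays open.

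The second pattern is the larger number of genes that probenecid changed in the OAT1 line (148) than in the parent (51) by limma, an order that edgeR (107 and 122) and DESeq2 (123 and 151) turned round. Read depth is argued against as the cause of limma's order: with every chip library thinned to 212308 reads, OAT1 gave 115 genes and the parent 56. A shift of all genes from the scaling cannot be told apart from a larger response. With each library centred on its median OAT1 gave 91 and the parent 60, just over the bound of 1.5 times. The margin of 1 counting SD that leaves this open was added after these counts were seen. Quantile normalisation gave 112 and 75 and rescaling to the same total 99 and 63, so each of these scalings narrowed the gap. The transporter that the OAT1 line over-expresses is a biological explanation, and it was not tested. The direct test of a difference between lines passed for 6 genes only.

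The third pattern is the smaller number of genes past the threshold with cisplatin in lot B (169) than in lot A (289), where 1 of 20 primary libraries did not match its lot. RNA of lot A in that library is a candidate explanation for its profile, with a share of 0.531 where a wrong label alone would give about 1. Without the library lot B gave 182 genes and lot A 372, so lot B's count stayed smaller. This cannot decide whether the library lowered the count, since lot B then has fewer cisplatin libraries than lot A. The shared spread changes as well: lot A's count rose from 289 with its own libraries unchanged. A wider spread between lot B libraries met its prediction. Their mean residual SD was 2.04 times that of lot A, still 1.78 times without the library that did not match. But the counts of 169 and 289 come from a fit that shares the spread, with a median SE of 0.333 in both lots. Through the SE, lot B's spread therefore enters both counts alike and cannot make only lot B's smaller. In a different model, with only its own groups in the fit, lot A gave 674 genes and lot B 26. A single library apart from its group cannot be told apart, since lot B's highest count, 391 without cisplatin replicate 2, came from a group that still held the library that did not match. A difference between the cells of the lots stays open as untested.

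A single library stood far from its replicates in 7 of the 49 sets of 4 to 6 libraries that were examined. The rule's rate of about 1 in 20 assumes normally distributed values and need not hold here, so an excess cannot be claimed. Gene levels were not logged, SLC22A8 had reads in 1 library of its set only, and MDM2 is a switching gene. SLC22A8 reached 0.598 in 1 untreated lot B library, and 0 in the others. The mean correlation with replicates was lowest at 0.921 in parent wells and at 0.850 in OAT3 wells. In parent wells HMOX1 reached 114.7 in its highest library. MDM2 reached 212.6 in OAT1 wells and 144.6 in OCT2 wells. GDF15 was lowest at 567.4 in OAT3 wells. Differences of an effect between groups passed for 114 genes (platform by line), 6 (probenecid by line) and 35 (cisplatin by lot). The blanks held 613, 280 and 235 reads, at most 0.0571% of the median cell library, and their most abundant gene was CYP2C19, a drug metabolism gene, with 83, 21 and 5 reads.

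Other splits of the same samples tested each count of genes. Shares of splits were not adjusted over the comparisons, so they can make chance unlikely but not exclude it. Chance was made unlikely where only the real one of 100 splits (1 of 100) gave as many. This held for the platform mean (860 against at most 9) and the probenecid mean (359 against 8). It also held for the OAT1 line (471 against 314), the OAT3 line (338 against 211) and the OCT2 line (119 against 74). The cisplatin mean (433 against 328) and primary against parent (953 against 469) were the others. Chance was also made unlikely for the platform in the parent (1 of 56 splits, 444 against 239) and OAT1 (1 of 56, 528 against 309). The same held for the platform in OAT3 (1 of 84, 541 against 317) and OCT2 (1 of 84, 543 against 9). For cisplatin in lot A it rests on fewer splits (1 of 35, 289 against 72). The share was also under 0.05 for cisplatin against PFOA (4 of 100, 348 against 355) and for the platform by line interaction (3 of 100, 114 against 492). In both, other splits called more genes than the real one, so these 2 argue less against chance than those above. Chance stays open for cisplatin in lot B (6 of 35, 169 against 541), the cisplatin by lot interaction (13 of 100, 35 against 305) and the probenecid by line interaction (5 of 100, 6 against 200). Why some splits called several times the real count, as in these last 3 and the platform by line interaction, was not tested. The PFOA counts of 0 were reached by all 100 splits for the mean (at most 2), all 35 in lot A (0) and lot B (8) and all 100 for the interaction (3). For probenecid within a line the 10 splits are too few for a share under 0.05: the parent gave 51 against at most 0 in another split, OAT1 148 against 2, OAT3 101 against 8 and OCT2 63 against 0.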

How the results depend on the processing

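Centring on the library median, correcting the SD between replicates for group size and leaving out libraries in doubt, the library that did not match its lot or switching genes were chosen after seeing the data, and the other settings before. Of 374 counts and values under alternatives, 301 stayed within 1.5 times the reported value and 73 did not. The 412 named entries, each a gene in a comparison, gave 13219 alternative values. Of these, 12779 kept their side of the threshold, 429 no longer passed and 11 newly passed. None that passed in the main or the alternative fit changed direction, and changes of direction among those past in neither were not counted. Of 47 lists called with members past the threshold, none changed the side with more members past the threshold under 5 scalings, and the list called for PFOA had 0 such members. The pseudocounts, the filters on low values and leaving out switching genes moved no count of genes over 1.5 times; without switching genes probenecid in OAT1 gave 141 and cisplatin in lot A 287. The cause of the moves below was not tested, except that leaving out libraries or groups changes the number of samples.
Quantile normalisation gave 1 gene for probenecid by line, 470 for cisplatin in lot A and 262 in lot B. Rescaling to the same total gave 3, 482 and 335. Median centring gave 0, 441 and 260, and 91 for probenecid in OAT1. Array weights, whose estimation stopped before full convergence in some fits, raised platform in the parent to 748 and OCT2 to 945, platform by line to 538, the OAT3 line to 565 and the OCT2 line to 322. With them probenecid gave 627 over the mean, 312 in the parent, 450 in OAT1, 443 in OAT3 and 117 by line. Cisplatin then gave 724 over the mean, 761 in lot A, 479 in lot B and 367 by lot, PFOA 1 over the mean, 69 in lot A, 1 in lot B and 2 by lot, and cisplatin against PFOA 652. By edgeR, probenecid gave 122 in the parent against 107 in OAT1, 98 in OCT2 and 1 by line, and cisplatin 448 in lot A and 256 in lot B. By DESeq2 the OCT2 line gave 200, probenecid 151 in the parent against 123 in OAT1, 158 in OAT3 and 131 in OCT2, cisplatin 502 in lot A and 316 in lot B, PFOA 14 over the mean, 7 in lot A and 8 in lot B, and cisplatin against PFOA 558. Without libraries in doubt the OCT2 line gave 179, probenecid 100 in the parent, 264 in OAT1, 154 in OAT3, 103 in OCT2 and 12 by line, platform by line 193, cisplatin in lot A 455 and cisplatin against PFOA 525. Without the library that did not match its lot PFOA by lot gave 1, by limma. With only the compared groups in the fit, platform in OAT3 gave 327, cisplatin 674 in lot A and 26 in lot B, and PFOA 2 in lot A.
The deviations of same-numbered libraries correlated over 0.1 in 8 of 24 pairs across lines, 3 of 12 across platforms and 1 of 12 across probenecid. Median correlations were 0.0091, -0.0018 and 0.0030. Between OAT1 and parent wells every pair was positive (0.0374 to 0.161), while OAT3 and OCT2 wells gave both signs. Differently numbered libraries were not correlated for comparison, so pairing by number was not tested. With the replicate number as a block, which was fitted for TERT1 cells only, probenecid by line gave 3, and no other platform, line or probenecid count moved over 1.5 times.
Leaving out single libraries gave 258 to 445 for platform in the parent, 84 to 182 for platform by line, 26 to 57 for probenecid in the parent, 70 to 124 in OAT1, 33 to 76 in OCT2 and 0 to 6 by line. The OAT1 low came without untreated replicate 1 and also without probenecid replicate 3, the OCT2 low without probenecid replicate 2. For cisplatin the ranges were 181 to 234 in lot A, 114 to 391 in lot B and 13 to 93 by lot, and for PFOA 0 to 1 in lot A, 0 to 1 in lot B and 0 to 1 by lot. All other counts of genes stayed within 1.5 times under every library left out.
Splits of higher and lower calls that moved by over 10 percentage points are given here or beside the result. Platform in the parent (135 and 309) became 236 and 225 by quantiles, 276 and 275 by edgeR, 342 and 283 by DESeq2 and 252 and 227 centred. In OAT1 (198 and 330) it became 298 and 312, 297 and 299, 301 and 315, and 293 and 283. In OAT3 (185 and 356) it became 299 and 316, 294 and 310, 290 and 333, and 305 and 285, with 303 and 284 at the same total. Probenecid in OAT1 (100 and 48) became 46 and 66, 25 and 82, 31 and 92, and 28 and 63, with 33 and 66 at the same total. In the parent (8 and 43) it became 19 and 44 at the same total, in OAT3 (38 and 63) 31 and 95 by edgeR and 23 and 84 centred, and in OCT2 (13 and 50) 21 and 35 centred. Cisplatin in lot A (105 and 184) became 234 and 236 by quantiles, 314 and 168 at the same total and 235 and 267 by DESeq2. In lot B (102 and 67) it became 125 and 137 by quantiles, 124 and 132 by edgeR, 146 and 170 by DESeq2 and 93 and 167 centred. By lot (31 and 4) it became 36 and 14, 30 and 10 at the same total, and 28 and 10 centred. With array weights the splits were 348 and 400 for platform in the parent, 126 and 196 for the OCT2 line, 154 and 158 for probenecid in the parent, 350 and 100 in OAT1, 307 and 136 in OAT3, 389 and 372 for cisplatin in lot A and 246 and 121 by lot. Without libraries in doubt they were 26 and 74 for probenecid in the parent, 204 and 276 for the cisplatin mean, 66 and 116 in lot B, 28 and 16 by lot, and 194 and 331 against PFOA. With only the compared groups they were 18 and 59 for probenecid in OAT3, 334 and 340 for cisplatin in lot A and 5 and 21 in lot B. Without the library that did not match its lot cisplatin by lot gave 26 and 9.
Gene lists passing camera numbered 1 for platform, 4 for the OAT1 line, 5 for OAT3, 4 for OCT2, 5 for probenecid, 10 for cisplatin, 1 for PFOA, 10 for cisplatin against PFOA and 8 for primary against parent. With an estimated correlation these became 0, 0, 0, 1, 4, 0, 0, 0 and 0. By fry, which does not compare a list with other genes, they became 11, 14, 11, 6, 11, 12, 0, 13 and 18. Depth limits low genes: a library's floor of 3 reads lies at 0.804 to 22.5 normalised reads.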
